A study of Homo sapiens with 6 samples.

How the data were processed

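RNA from human neutrophils stimulated with lipopolysaccharide (LPS) was hybridised together with RNA from non-stimulated neutrophils on 6 2-colour arrays. Per the labels, the stimulated RNA carried the dye Cy3 and the non-stimulated RNA the dye Cy5 on every array. The titles place the arrays in 3 sets, each with a repeat A and a repeat B. A time of 4 h is given for the stimulated RNA of set 2 and set 3, and none for set 1. The labels do not state that repeats or sets were separate cultures or donors.

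The deposited values are log10 ratios. The labels call them ratios of stimulated over non-stimulated signal, which sets their direction, and the scale was settled from the values. Raising 10 to the power of each value gave a multiple of 0.01 for 100% of the values, within a tolerance of 0.01 of that step, and neither base 2 nor base e did. The background correction, the normalization between dyes and the software are not given in the sources used here, and whether the authors centred the arrays remains unknown. The deposited median ratio was 0.81 on array A and 0.87 on array B of set 1, 1.00 and 0.97 in set 2, and 1.04 and 1.02 in set 3. Channel intensities were not used here, so how far each spot stood above background is unknown. The number of arrays limits the precision.

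The log10 ratios were multiplied by the base-2 logarithm of 10 to give log2 ratios, and each array was centred on its median. All changes are therefore relative to the median feature of the array. Gene symbols came from the platform annotation, which is old, and were updated through Entrez identifiers with the gene table of the assembly GRCh38.p14. Of 4608 probes, 3383 had 1 symbol, of which 3377 were matched by identifier; 236 had several symbols and 989 had none. Probes with the same single symbol were averaged, giving 2727 genes, 508 of them with more than 1 probe. The other 1225 probes were tested unnamed, for 3952 features in all. No value was missing.

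Repeats A and B of a set were averaged, so that n = 3. The log2 ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, then eBayes, 2-sided), with Benjamini-Hochberg (BH) adjustment over all features and a threshold of 0.05. A limma F-test of the 3 set means took its spread from the repeats. In both tests the p-values measure only the spread between these samples, which may be technical. The dyes were never swapped, so dye and stimulation cannot be told apart at any probe.

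Before the data were examined, 23 gene lists were fixed, covering cytokines, NF-kB signalling, interferon response, granule proteins, receptors, respiratory burst, apoptosis, transcription factors, metabolism, ribosomal proteins, proteasome, antigen presentation, metallothioneins, coagulation, cytoskeleton and markers of other blood cells. The 19 lists with at least 3 measured members were tested with camera from limma at a preset correlation of 0.01, with BH adjustment over the lists. The pattern used for ribosomal proteins first admitted RPL7L1, which the written definition excludes, and it was corrected after values had been seen. The rule for named genes was fixed at the same time. It took the 15 largest rises and the 15 largest falls among genes with 1 symbol that passed the test with the same sign on all arrays. A direction with fewer than 10 such genes would have been filled to 10, and up to 3 measured members of each list with the largest absolute mean log2 ratio were added. This gave 79 genes. The text names part of the list members among them and covers the others in the counts of their lists, and 1 gene's result is not reported here. A further 31 genes are named outside the rule and were chosen after their values had been seen.

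The tests were also run on simulated data. In 20 simulations of 3952 features with 200 changed by stimulation, 56.7% of changes of 0.5 on the log2 scale were recovered, 91.8% of changes of 1 and 99.2% of changes of 2. Of the calls, 3.9% were false. For the test between sets, simulated on the same number of features, the recovered shares were 36.4%, 85.9% and 99.0%, and 3.31% of the calls were false. Simulations with no change, run for the comparison of stimulated with non-stimulated cells alone, gave a mean of 0 calls. Simulated features were independent, with normal noise at spreads taken from these data. They held no correlation between genes, no dye effect and no steady gap between repeats. The false share among the real calls may therefore be higher. Changes were also placed on features without regard to their spread. The recovered shares may thus be lower for real changes that vary more between sets.

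Alternatives tried were no centring, an equal median absolute deviation on every array, repeat A or B alone, a term for the repeat, every probe on its own, leaving out each set, all 6 arrays as separate samples, the set as a random block, other variance models, other thresholds, an estimated correlation and the test fry.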

Results

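Neutrophils are phagocytic granulocytes of the blood, and LPS is a cell-wall component of Gram-negative bacteria that they sense through Toll-like receptor signalling. Expression in LPS-stimulated human neutrophils was compared with that in non-stimulated neutrophils on 6 2-colour arrays of 4608 probes, in 3 sets of 2 repeats each. The labels give a time of 4 h for set 2 and set 3 and none for set 1. Every value is a log2 ratio of stimulated over non-stimulated signal, relative to the median of its array, and is given as mean ± SD over the sets (n = 3).

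Before centring, the ratios ran from 0.16 to 56.95. Across probes, which are not independent replicates, Pearson's r between repeats was 0.89 in set 1, 0.76 in set 2 and 0.70 in set 3. Spearman's correlation was 0.70, 0.61 and 0.63. After repeats were averaged, r across features was 0.72 between set 1 and set 2, 0.53 between set 1 and set 3, and 0.44 between set 2 and set 3, with Spearman's correlations of 0.46, 0.32 and -0.03. No 2 arrays were copies of each other, since at most 3.71% of values were identical in any pair.

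The first comparison asked which genes differed between stimulated and non-stimulated cells. IL1B, which encodes the pyrogenic cytokine interleukin-1 beta, and CCL3, a chemokine, rose most, by 3.20 ± 1.26 and 3.14 ± 0.71 on the log2 scale, or 9.17-fold and 8.83-fold. The interleukin-1 receptor antagonist gene IL1RN rose by 1.93 ± 0.98, the immune checkpoint ligand gene CD274 by 1.76 ± 0.82 and the NF-kB subunit gene NFKB2 by 1.40 ± 0.60. PSMB8, which encodes an immunoproteasome subunit, fell most among named genes, at -1.66 ± 0.19, followed by the calcium-binding protein gene S100A4 at -1.51 ± 0.18. The SD over set means leaves out the gap between repeats: PSMB8 averaged -1.17 on repeat A and -2.16 on repeat B, S100A4 -1.17 and -1.86, and IL1RN 2.50 and 1.36. With limma and BH adjustment, 168 of 3952 features changed, 60 upward and 108 downward, against 515 features at an unadjusted p under 0.05. The sign was the same on all 6 arrays for 57 of the 60 and 107 of the 108.

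Other leading rises were MGP, a matrix Gla protein gene, at 2.23 ± 1.18, STEAP2, a metalloreductase gene, at 1.73 ± 0.39, and the hyaluronan-binding protein gene TNFAIP6 at 1.68 ± 0.49. MAP3K8, a kinase gene of the LPS signalling pathway, rose by 1.22 ± 0.58. The potassium channel gene KCNJ2 rose by 1.16 ± 0.54 and the acyl-CoA synthetase gene ACSL1 by 1.14 ± 0.55. MGP and STEAP2 each rest on 1 probe with an old annotation and could be misassigned. The limma adjusted p (BH) was 0.00604 for IL1B, 0.000894 for CCL3, 0.019 for MGP, 0.0169 for IL1RN and 0.00137 for STEAP2.

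Among the falls were the histone gene H3-3A at -1.47 ± 0.73, the smooth muscle actin gene ACTA2 at -1.36 ± 0.16 and the clathrin adaptor gene AP2S1 at -1.30 ± 0.18. GAPDH, a glycolytic enzyme gene, lay at -1.26 ± 0.19, with its 4 probes between -1.42 and -1.07. The G-CSF receptor gene CSF3R fell to -1.12 ± 0.57. The remaining named falls were MSRB1 at -1.03 ± 0.26, TELO2, which was 2-fold lower with an SD of 0.20, SORL1 at -0.99 ± 0.08, SNX18 at -0.98 ± 0.21, TSC22D3 at -0.97 ± 0.19, FOS at -0.94 ± 0.44 and PXN at -0.93 ± 0.36. SORL1 averaged -0.60 on repeat A and -1.37 on repeat B, TSC22D3 -0.69 and -1.25, and PXN -1.14 and -0.73. The limma adjusted p (BH) was 0.000396 for PSMB8, 0.00113 for GAPDH and 0.0183 for FOS.

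**Figure D1:**
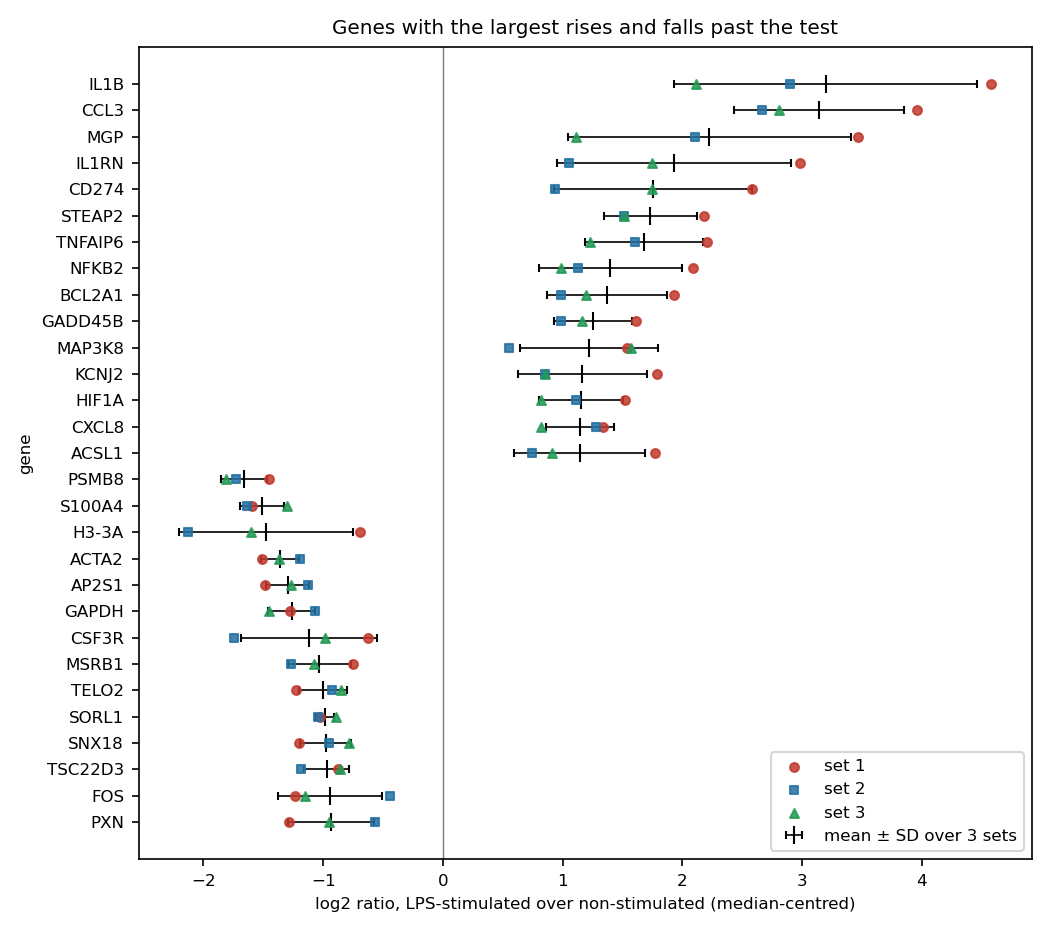
Log2 ratios of the 15 genes with the largest rises and 14 of those with the largest falls past the limma test, with each set as a coloured point and the mean ± SD over 3 sets in black. IL1B spans 2.11 to 4.58 across the sets, while PSMB8 spans -1.81 to -1.45.

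Of 18 measured genes for cytokines and chemokines, 4 rose and none fell, and adjusted over the list alone 5 rose and 1 fell. The 4 were IL1B, CCL3, IL1RN and CXCL8, the gene for the neutrophil attractant interleukin-8, which rose by 1.15 ± 0.28. The list mean was 0.72 ± 0.49, or 0.44 without set 1, and its median 0.19. Camera with BH adjustment placed the list above the other features (adjusted p = 0.000187), but adjusted p = 0.731 with an estimated correlation. IL6 and CCL2 did not pass the test, at 1.37 ± 1.57 and 1.17 ± 1.29. The 6 measured monocyte markers had a median of -0.03 and none passed.

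In the list for the NF-kB pathway and its feedback, 5 of 19 measured genes rose and none fell, and adjusted over the list alone 6 rose. Besides TNFAIP6 and NFKB2, these were the mitochondrial superoxide dismutase gene SOD2 at 0.90 ± 0.23, the precursor subunit gene NFKB1 at 0.79 ± 0.35 and the apoptosis inhibitor gene BIRC2 at 0.54 ± 0.19. Probes disagreed in sign for TNFAIP6 (-0.28 to 3.31), SOD2 (-0.02 to 1.81) and NFKB1 (-0.09 to 1.37). The camera adjusted p (BH) was 0.000364, and adjusted p = 0.731 with an estimated correlation.

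Ribosomal protein genes had a mean of -0.24 ± 0.14 and a median of -0.26 over 21 measured members. RPL37A alone passed over all features, at -0.51 ± 0.22, and adjusted over the list alone 8 fell and none rose. The camera adjusted p (BH) was 7.73e-06, and adjusted p = 0.731 with an estimated correlation.

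Receptor and adhesion genes of neutrophils moved in both directions, with 3 of 27 measured genes rising and 5 falling, and 4 and 6 adjusted over the list alone. The hyaluronan receptor gene CD44 rose by 0.91 ± 0.11, though its 3 probes ran from -0.29 to 1.53. The adhesion gene CD58 rose by 0.62 ± 0.24 and the interferon-gamma receptor gene IFNGR2 by 0.52 ± 0.22. Besides CSF3R, the falls were PECAM1 at -0.90 ± 0.25, FCGR3A at -0.89 ± 0.35, SELPLG at -0.70 ± 0.30 and the beta-2 integrin gene ITGB2 at -0.41 ± 0.10. FCGR3A has a near-identical paralog, FCGR3B, so its probe may report either gene.

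Transcription factors of the immediate early and stress list split in a similar way, with 3 of 25 rising and 4 falling, and 5 and 7 adjusted over the list alone. The hypoxia-inducible factor gene HIF1A rose by 1.15 ± 0.35, XBP1 by 0.65 ± 0.33 and ETS2 by 0.56 ± 0.24. FOS, the antiproliferative gene BTG1 (-0.85 ± 0.11), ATF4 (-0.73 ± 0.05) and NR4A3 (-0.49 ± 0.18) fell. Of 20 genes for apoptosis and survival, 2 rose and none fell, and adjusted over the list alone 2 rose and 1 fell. They were the BCL2 family gene BCL2A1 at 1.37 ± 0.50 and GADD45B at 1.26 ± 0.33.

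Granule protein genes included 1 fall among 11, S100A9 at -0.90 ± 0.37, and adjusted over the list alone 1 rose and 2 fell. Its partner S100A8 stood at -0.40 ± 0.44, with probes at -0.85 and 0.05, and did not pass; without set 1, where limma gave all features 1 common spread, it stood at -0.62 and passed (BH-adjusted p = 0.000865). None of 9 respiratory burst genes passed, against 1 in each direction adjusted over the list alone; GPX1 stood at -0.45 ± 0.27, passing without set 3 at -0.60, and CYBB at 0.36 ± 0.09. GAPDH was the only one of 6 glycolysis and hypoxia genes to pass, and PSMB8 the only one of 12 proteasome genes, with PSMB10 at -0.19 ± 0.19. Adjusted over the list alone, 1 glycolysis gene rose and 1 fell, and 1 proteasome gene fell.

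CD74, the invariant chain of class II antigen presentation, fell by 0.51 on the log2 scale, the only pass among 3 class II genes, and adjusted over the list alone 1 rose and 2 fell. MYL6, at -0.54 ± 0.22, was the only pass among 11 cytoskeleton genes, where 2 fell adjusted over the list alone. ACTB stood at 0.06 ± 0.07 and VIM at 0.00 ± 0.17, both with means below 0 when arrays were not centred. No gene passed among 8 of oxidative phosphorylation, 4 metallothioneins and 11 of coagulation and proteolysis, by either adjustment. CANX, the 1 measured gene of the class I list, did not pass, and that list was not tested.

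Markers of other blood cells gave few calls. IL2RB fell by 0.46 on the log2 scale, the only pass among 5 T and NK cell markers. None passed among 6 platelet, 2 B cell, 1 eosinophil and basophil, and 1 erythroid marker, nor among the 6 monocyte markers. Adjusted over the list alone, 1 T and NK cell marker and 1 B cell marker fell, and 1 monocyte marker rose. Besides cytokines, NF-kB and ribosomal proteins, no list passed camera.

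**Figure D2:**
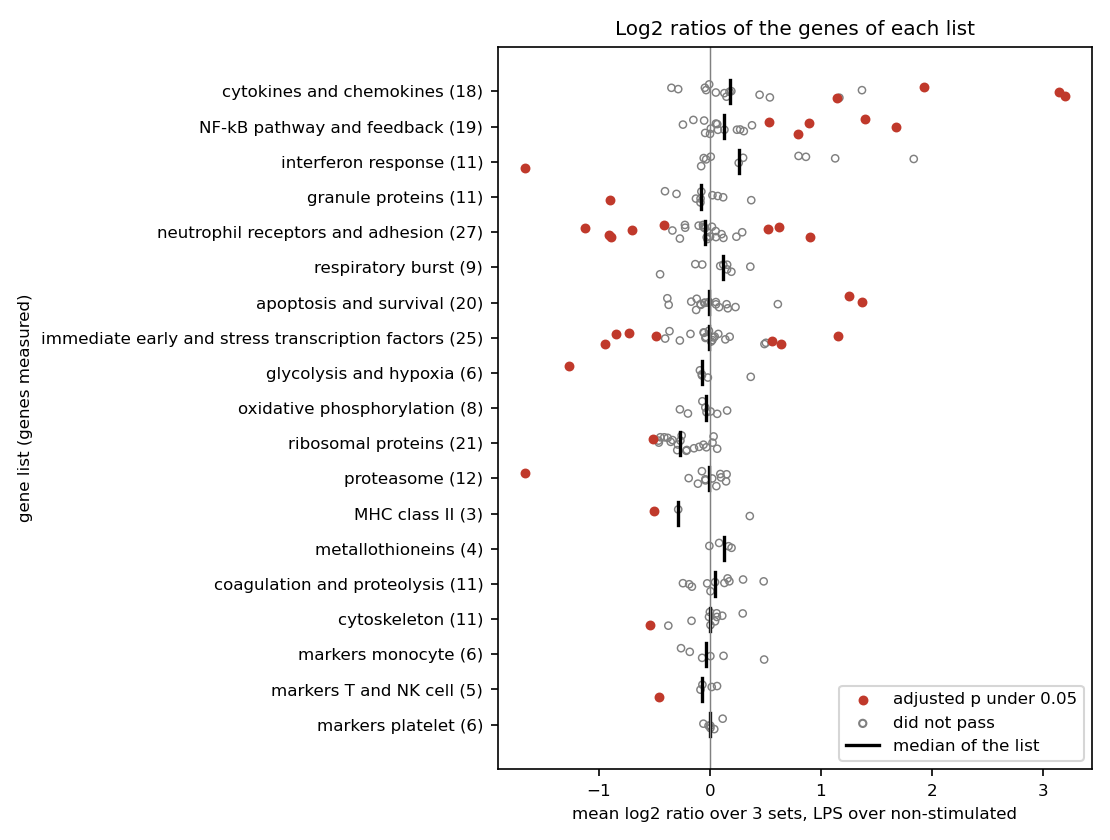
Mean log2 ratios over 3 sets of the members of each list with at least 3 measured genes, with passes of the limma test filled, other members open, and a bar at each list's median. Ribosomal proteins have a median of -0.26, while cytokines spread from -0.35 to 3.20.

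Repeats A and B were also compared after their values had been seen. Their means differed by over 1.5 times on the log2 scale for 51 of the 168 changed features and 14 of 58 named ones. Besides those above, these were MAP3K8 (0.89 on A and 1.55 on B), CXCL8 (1.66 and 0.64), FCGR3A (-1.27 and -0.50), ATF4 (-0.97 and -0.49), IFNGR2 (0.42 and 0.63), ETS2 (0.44 and 0.67), CLIC4 (0.72 and 1.42) and FOLR3 (-0.82 and -0.51). In a limma test of the difference (BH), 15 of 3952 features passed, 13 of them among the 168, against 269 at an unadjusted p under 0.05. PSMB8, S100A4, IL1RN, SORL1, MAP3K8, CXCL8, FCGR3A and CLIC4 passed, with an adjusted p of 0.000862 for PSMB8.

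The calls rest on sharing the spread across features: with no such moderation, none passed adjustment and 354 had an unadjusted p under 0.05. With a trended variance IL1B, CCL3, MGP, IL1RN, CD274, PSMB8, S100A4, H3-3A, ACTA2, CD58, IFNGR2, NFKB1, BIRC2, ETS2, XBP1 and TANK did not pass, nor did IL1B, MGP, IL1RN, CD274, H3-3A and CSF3R with robust moderation. The trend was fitted on the mean log2 ratio, the tested value itself, and not on spot intensity. Losses under the trend therefore do not tell how well a large change was measured. Without set 2, the limma test (BH) called 51 features and 20 of the 39 named passes were lost, among them IL1B (adjusted p = 0.0875), MGP, TNFAIP6, NFKB2, KCNJ2, HIF1A, CXCL8, ACSL1, H3-3A, CSF3R, MSRB1, SNX18, SOD2, S100A9, PECAM1, RPL37A, CD74, MYL6 and IL2RB. Without set 3 the test called 419 and lost none. It then gained 10 genes named by the rule: MX1, IFIT1, CTSH, GPX1, PIM1, RPL11, RPL6, HLA-DPB1, SERPINB9 and the B cell marker CD37. Without set 1, on 1 common spread, it gained 4: MX1, IFIT1, S100A8 and CD37. The ratios themselves moved less: leaving out any 1 set moved none of the 58 named passes by over 1.5 times, and without set 2 IL1B stood at 3.35, NFKB2 at 1.54 and ACSL1 at 1.34. The test that called these genes favours a small spread over the same 3 sets, so large moves were unlikely from the outset. Also lost without set 2 were CD58, IFNGR2, FCGR3A, SELPLG, ITGB2, NFKB1, BIRC2, ETS2, XBP1, ATF4 and NR4A3, and RPL37A, IL2RB, IFNGR2, ITGB2, BIRC2, XBP1 and NR4A3 did not pass without set 1 either.

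The second comparison asked whether the response differed between the sets. Among interferon-response genes, MX1, an antiviral GTPase gene, had log2 ratios of 3.66 in set 1, 1.92 in set 2 and -0.07 in set 3, and IFIT1 had 2.29, 1.11 and -0.02. The related genes MX2, at 1.96, 0.91 and -0.28, and OAS1, at 0.89, 0.26 and -0.37, followed the same order of sets, as did GBP2 (1.80, 0.38 and 0.21) and IRF2 (0.58, -0.17 and -0.57). These 6 of the 11 measured list members passed the limma F-test, with a BH-adjusted p of 5.76e-06 for MX1, and each was highest in set 1 and lowest in set 3. The IFIT1 values average 2 probes that disagreed, with means over the sets of 0.06 and 2.20.

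Over all sets together the interferon list did not pass, with a mean of 0.31 ± 0.63, a median of 0.26 and a camera adjusted p (BH) of 0.453. Its set means were 0.94, 0.28 and -0.31. PSMB8 was its only pass, by either adjustment, and its ratio was below 0 in every set. Without set 3 the list passed camera (adjusted p = 0.00207), and in the limma test (BH) MX1 and IFIT1 then passed with means of 2.79 and 1.70. The list mean was 0.61 without set 3. Without set 1, on 1 common spread, MX1 and IFIT1 passed at 0.92 and 0.55. Without centring, where limma again gave all features 1 common spread, the list had a lower mean of 0.23. It passed camera there as well (adjusted p = 0.00146). It did not pass without set 1 (0.981, with a mean of -0.01), without set 2 (0.796) or with an estimated correlation (adjusted p = 0.810).

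IL6 and CCL2 also differed between sets, at 3.11, 0.95 and 0.05 and at 2.63, 0.67 and 0.20 in sets 1 to 3. IL1B stood at 4.58, 2.90 and 2.11, IL1RN at 2.99, 1.06 and 1.75, and CD274 at 2.58, 0.94 and 1.75. Without set 3, IL6 passed with a mean of 2.03 (limma, BH-adjusted p = 0.00165) and CCL2 with a mean of 1.65 (0.00348). Without set 1, limma gave all features 1 common spread, which ignores the gap between 0.95 and 0.05. On that spread IL6 passed at 0.50 (limma, BH-adjusted p = 0.0175). CSF3R was closest to 0 in set 1, at -0.63, against -1.74 in set 2 and -0.99 in set 3. In all, 537 of 3952 features differed in the limma F-test (BH), or 13.6%, of which 356 were highest in set 1, 18 in set 2 and 163 in set 3. Of the 60 features that rose over all sets, 58 were largest in set 1 and 30 differed between sets, while of the 108 that fell, 57 were most negative in set 1 and 16 differed between sets. Centring raised every ratio of set 1, where the deposited median ratios were 0.81 and 0.87. The counts by set may therefore depend on centring, and they were not repeated without it. The repeats give the F-test its spread, so it shows only that sets differed by more than repeats did. The steady gap between repeats A and B at some genes enters that spread; with the repeat as a term, chosen after seeing the data, 719 features differed, the 537 among them. Without centring 1879 features differed, while 336 did without set 1, 334 without set 2 and 135 without set 3. In a test chosen after the sets were seen to differ, interferon-response genes, cytokines and the NF-kB pathway stood higher in set 1 than in set 3 relative to other features (camera, BH-adjusted p = 5.29e-09, 6.15e-09 and 0.000148) and ribosomal proteins lower (5.23e-05). The adjusted p was 0.133, 0.185, 0.491 and 0.161 with an estimated correlation. Like the F-test, this camera test took its spread from the repeats, which may be technical, and compared 1 set with 1 other. Its p-values therefore do not measure how far further sets would differ.

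**Figure D3:**
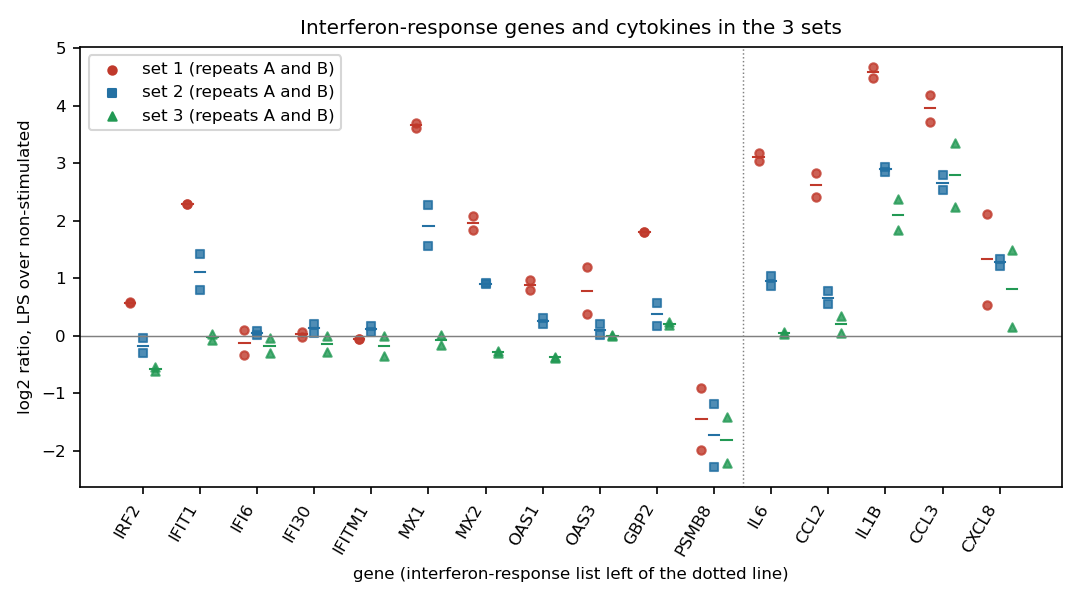
Log2 ratios of the 11 interferon-response genes and of 5 cytokine genes on each array, with 2 points per set for repeats A and B and a short line at their mean. MX1 runs from 3.66 in set 1 to -0.07 in set 3, and PSMB8 lies below 0 in all 3 sets.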

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

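The test on interferon-response genes and that of a single factor for set 1 were chosen only after their values had been seen, as were 31 of the genes counted below; the tests of the other explanations were written down before their results, though after a first look at the most extreme mean ratios.

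A gene or list on 6 arrays was singled out when its highest or lowest array lay far from the rest. Chance gives this for about 1 in 20 if the 6 values are independent. Of 129 genes and lists tested, 7 were singled out, against 6.45 by chance under independence. Without the 31 genes it was 4 of 98. Repeats of a set were correlated and many genes differed between sets, so the chance figure does not hold here. CD44 was 0.52, CD58 0.070, ETS2 -0.0145 and TIFA 0.23 on array A of set 2, each the lowest of its arrays. CYBB was 0.64 on array B of set 3, the highest of its arrays. The respiratory burst list had a mean of 0.14 on array A of set 1 and the oxidative phosphorylation list a mean of 0.10 on array A of set 3, both the highest.

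Differences between sets, by the limma F-test with BH adjustment, were found for 41 of 110 genes. Of these, 27 were among the 79 genes named by the rule and 14 among the 31 others, several of which were picked because they differed, so the share cannot be set against the 13.6% of all features. The span between the highest and lowest set, on the log2 scale, was 3.73 for MX1, 3.06 for IL6, 2.47 for IL1B, 2.43 for CCL2, 2.36 for MGP, 2.31 for IFIT1 and 2.24 for MX2. It was 1.93 for IL1RN, 1.78 for RNF213, 1.72 for TNFSF10, 1.71 for PARP9, 1.65 for CD274, 1.59 for GBP2, 1.44 for H3-3A, 1.29 for CCL3, 1.27 for OAS1, 1.23 for NAMPT and 1.16 for IRF2. Spans near 1 were 1.12 for CSF3R, 1.10 for both NFKB2 and PIM1, 1.02 for both MAP3K8 and ACSL1, 0.98 for TNFAIP6, 0.95 for BCL2A1 and 0.93 for KCNJ2. The smaller ones were 0.89 for S100A8, 0.85 for MT1X, 0.79 for FOS, 0.74 for S100A9, 0.71 for SERPINB9, 0.70 for HIF1A, 0.67 for STEAP2, 0.64 for LGALS3, 0.62 for NFKB1, 0.60 for SELPLG, 0.59 for XBP1, 0.55 for MS4A1, 0.53 for TANK and 0.50 for GPX1.

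Set 1 had the widest log2 ratios, with an SD over features of 0.38 against 0.28 in set 2 and 0.27 in set 3. Interferon-response genes were singled out after their order over the sets had been seen. The slope of set 3 on set 1 was 0.05 over these 11 genes. It was 0.52 over 38 other features with a mean log2 ratio over 1 in sets 1 and 2. The difference was -0.471 (95% bootstrap interval -0.674 to -0.111), and without centring it was -0.488 (-0.728 to -0.0582). In these 3 sets the list thus departed from the slope of the other features. Because that order led to the choice of the list, the test gives no independent evidence against 1 factor between sets. The median gap between set 3 and its prediction was -0.84 (-1.22 to -0.15) with centring, and -0.71 (-1.19 to 0.04), an interval that holds 0, without. The intervals in this paragraph resample genes that were all measured in the same 3 sets. They treat the genes as independent and do not measure how far other sets would differ. Over all features a single factor for set 1 stays open in a pooled test of slopes. The slope of set 1 on the mean of sets 2 and 3 was higher over the rises than over the falls. The difference was 0.516 (0.366 to 0.682) with centring and 0.139 (-0.0389 to 0.327) without. The rises and falls were those called from these same 3 sets, 60 and 108 with centring and 88 and 211 without. Centring also raised every ratio of set 1, which makes rises larger and falls smaller there. A pooled slope hides single genes that depart from 1 factor. H3-3A fell less in set 1 (-0.69) than in set 2 (-2.13) or set 3 (-1.60). IL6 rose far more in set 1 (3.11) than in set 2 (0.95) or set 3 (0.05). A planned count was set aside, since sets 2 and 3 also differed, in 336 features. The stimulation time, stated for 2 of the 3 sets, stays open too, as do day, array and donor, which cannot be told apart from set here, and a biological cause was not tested.

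GAPDH and most ribosomal protein genes had log2 ratios below 0, and a dye bias against bright spots is a possible explanation. The ribosomal protein list had a median of -0.264 (95% bootstrap interval -0.352 to -0.142); the bias was said to need a median under -0.3 and to be excluded by one above -0.1, so this value lies between. Of a panel of 16 abundant transcripts fixed for this test, 3 were measured, and they did not share a direction: SRGN rose by 0.80 (limma, BH-adjusted p = 0.00765), LCP1 stood at 0.05 and PFN1 at -0.37. Without a dye swap, dye and stimulation cannot be told apart.

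IL6 and CCL2, known also as monocyte products, were higher with LPS in set 1, and RNA from monocytes could contribute. The 6 monocyte markers had a median log2 ratio of -0.0319 (95% bootstrap interval -0.220 to 0.306). A ratio does not give the share of monocyte RNA in either channel, so this stays open.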

How the results depend on the processing

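The median over the probes of a gene, and in the comparison between sets leaving out a set or a term for the repeat, were chosen after seeing the data; a value on all 6 arrays changes nothing, since none was missing. Against 168 changed features (60 higher, 108 lower; limma, BH), the counts were 299 with 211 lower without centring; 75, with 24 higher and 51 lower, at an equal median absolute deviation; 72, with 29 and 43, from repeat A alone; and 109, with 66 lower, from repeat B alone. Testing every probe gave 165 lower and all 6 arrays as separate samples gave 387 (128 and 259). A variance trended on the mean log2 ratio gave 26 higher and 210 lower, and an adjusted p under 0.10 gave 164 lower. A mean change of at least 2-fold as well left 45 (28 and 17), and a change over 2-fold in all 3 sets, with no test, held for 23 (14 and 9). No moderation gave 0 changed, 0 higher and 0 lower, with 354 at an unadjusted p under 0.05. Leaving out 1 set gave 51 to 419 changed, 26 to 236 higher and 25 to 183 lower, lowest without set 2 and highest without set 3. All 168 were also called without centring, on a spread common to all features, with all arrays separate and without set 3, and 157 were among the 236 with the set as a random block (correlation within a set of 0.456). Of the 39 passes named by the rule, 23 were kept at an equal median absolute deviation (lost were IL1B, MGP, IL1RN, CD274, NFKB2, MAP3K8, KCNJ2, CXCL8, ACSL1, CSF3R, FOS, PXN, RPL37A, CD74, MYL6 and IL2RB), 28 and 26 with repeat A or B alone, 37 without set 1, 19 without set 2, 33 with robust moderation and 30 with a trended variance. Without set 1, and also without centring, limma gave all features 1 common spread, so that MX1, IFIT1 and IL6 passed in both, MX1 with 1.92 and -0.07 in the sets other than set 1 and with an adjusted p of 1.27e-32 without centring, where MX2, GBP2 and CCL2 passed too. Without set 3, MX1, IFIT1, MX2, OAS1, GBP2, IL6 and CCL2 passed. Of the 19 passes named outside the rule, 17 were lost without set 2. No gene or list named as past its test turned direction without centring or at an equal median absolute deviation. When every probe was tested, the lower of the 2 SOD2 probes stood for the gene, at -0.020. The other probe was at 1.81, so the turn in sign comes from that choice. The 3 lists passed camera under every centring, scaling, repeat, probe and left-out set tried, but 0 lists passed with an estimated correlation (adjusted p = 0.731 for each) and 0 with fry (0.376 for cytokines and chemokines, 0.369 for the NF-kB pathway and 0.340 for ribosomal proteins). The interferon list passed camera without centring (0.00146) and without set 3 (0.00207), over a range of 0.00146 to 0.981, and glycolysis and hypoxia passed with every probe tested on its own (0.000658), over a range of 0.000658 to 0.731 for that list. With every probe on its own, GAPDH counted 4 times in the glycolysis and hypoxia list, with probes between -1.42 and -1.07. Features that differed between sets numbered 1879 without centring, 719 with a term for the repeat, and 135 to 336 without 1 set, against 537. The cause was not tested, except where fewer samples, a fixed spread or the counting of probes is the alternative itself. Signal over background was not used here, so what dim spots limit is unknown.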

Other observations

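All genes in this part were chosen after their values had been seen, and the test of the count against other sign assignments was planned. The TRAF-interacting adaptor gene TIFA rose by 0.89 ± 0.32 and TANK, another TRAF partner, by 0.73 ± 0.29. The granule proteoglycan gene SRGN rose by 0.80 ± 0.22 and the chloride channel gene CLIC4 by 1.07 ± 0.22, each on all 6 arrays. Among surface and secreted proteins of granulocytes, the adhesion gene ICAM3 fell by 0.68 on the log2 scale, the folate-binding protein gene FOLR3 by 0.66 and the neprilysin gene MME by 0.50. The glucocorticoid receptor gene NR3C1 stood at -0.45 ± 0.10 and its known target TSC22D3 at -0.97 ± 0.19, both past the limma test (BH). Without set 2, TANK, SRGN, ICAM3, FOLR3, MME and NR3C1 no longer passed, and NR3C1 did not pass without set 1 either.

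Genes outside the interferon list followed the same order of sets as MX1. RNF213 had log2 ratios of 1.44, 0.53 and -0.34 in sets 1 to 3, PARP9 had 1.49, 0.57 and -0.21, and TNFSF10 had 1.34, 0.39 and -0.39. NAMPT, the gene of an NAD biosynthesis enzyme, had 0.95, 0.47 and -0.29. None of these 4 passed over all sets together. PARP9 and RNF213 each passed in 2 of 13 alternative settings, the one without set 3 included. They were chosen for their order over the sets, so that their passing the limma test (BH) without set 3, where 419 features were called, says little; their means there were 0.98 for RNF213, 1.03 for PARP9, 0.87 for TNFSF10 and 0.71 for NAMPT.

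With 3 sets there are 4 ways to assign signs to them, too few for a share under 0.05. The real assignment gave 168 changed features and the highest other gave 0, so 1 of the 4 gave as many.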
